A study of Arabidopsis thaliana with 3 samples.

How the data were processed

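RNA from the base of the inflorescence stem of Arabidopsis thaliana was compared between wild type and plants carrying T-DNA insertions in both NST1 and NST3, which encode NAC-domain transcription factors. The labels number the mutant samples nst1-1 nst3-1 #1, #2 and #3, called lines 1, 2 and 3 here. All 3 carry the same allele names, so they are not taken as independent insertions. Per the labels, the lowest 4 cm of the stem was taken from stems 12 to 17 cm tall. Plants grew under 8 h of light and 16 h of dark. Each line was hybridised together with wild-type RNA on 1 two-colour array. The mutant carried Cy5 on the arrays of lines 1 and 3 and Cy3 on the array of line 2. The labels do not say whether the wild-type RNA of the 3 arrays was 1 extract or several.

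The values used were the authors' deposited log ratios, 1 per spot and array, for 22236 spots. The deposited ratios were read as log10 of Cy5 over Cy3. The base was not given in the sources used here; it was inferred from a lower bound at exactly -2, which is a 100-fold ratio on a log10 scale. All fold and log2 values rest on that reading, while the p-values of the fit do not depend on it. The scanner, the background correction and the dye normalization were not given in the sources used here. The median of the deposited values was 0 on every array over all spots. Over the spots with 1 listed gene it was 0.00294, -0.00295 and 0.00396 for lines 1, 2 and 3, so the columns were centred or dye-normalized by a method that stays unknown. Spot intensities were not used here, so dim and saturated spots were not identified, and signal over background was not judged. The number of arrays, 3, limits the precision.

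The direction of the ratios was not stated with the values, and Cy5 over Cy3 is a reading that no value here tests. That the array of line 2 is opposite to the others rests on the dyes named in the labels and on the correlation of the deposited columns across genes. This correlation was -0.488 between lines 1 and 2 and -0.784 between lines 2 and 3. It was 0.477 between lines 1 and 3, the pair with the same dye orientation. The sign of the array of line 2 was turned so that every value was mutant over wild type, and log10 ratios were converted to log2. If the deposited ratios were Cy3 over Cy5, every direction below would be turned.

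Spots were named through the platform's probe annotation, with symbols updated through Entrez identifiers against the gene table of assembly TAIR10.1. Of the 22236 spots, 9335 had 1 listed gene, 40 had several and 12861 had none listed. Of the 9335 spots, 9317 had an identifier in the gene table and 18 did not. Spots with several genes or none were not named. Spots of 1 gene were averaged, which concerned 79 genes with more than 1 spot, and gave 9253 genes with a value on all 3 arrays. For 7944 genes the name was the locus code. No genome build was given in the sources used here, so no coordinates are printed, and the gene table served only for names and for the order of neighbouring genes.

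The main test was limma (version 3.58.1, R 4.3.3), with lmFit and eBayes on the 3 log2 ratios of each gene against 0, two-sided, and a Benjamini-Hochberg adjusted p under 0.05. Each line counted as 1 replicate. Wild-type RNA was on every array and no wild type was set against it, so the test has no separate estimate of the spread of the wild type, and leaves that spread out if the wild-type RNA was 1 extract. With 2 arrays of one dye orientation and 1 of the other, a dye effect of a spot cancels only in part. Genes at least 2-fold changed in the same direction on all 3 arrays were counted without a test. Errors are SDs over the 3 lines. Agreement between arrays was described with Pearson and Spearman correlations across genes, which are not independent replicates.

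Before the data were examined, 23 gene lists with 303 genes were fixed, and 51 of these genes were measured. The lists covered the targeted genes, secondary-wall cellulose, xylan, monolignol biosynthesis, laccases and peroxidases, secondary-wall transcription factors, vessel NAC and related factors, xylem cell death, fibre fasciclins, primary-wall cellulose, expansins, xyloglucan endotransglucosylase/hydrolases (XTH), light harvesting and Rubisco, phloem, cambium, epidermis and cuticle, flavonoids and anthocyanins, salicylate defence, jasmonate and wounding, water stress, the G2/M cell cycle, auxin response, and reference genes. Members were counted as higher, lower or not called, over all genes and adjusted over the list alone. The 5 lists with at least 5 measured genes were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, which tests a list against no change, as alternatives. With an estimated correlation, camera also uses the residual degrees of freedom of the 3 arrays and not those of the genes. A call lost there need not be lost through correlation. The naming rule, also set then, took the 2 targeted genes, the 8 largest mean decreases and 8 largest mean increases among called genes with 1 sign on all 3 arrays, and up to 4 measured members of each list with the largest absolute mean. Of the 8 largest decreases, 1 is not reported here. After the annotation had been seen, 38 gene families were formed from symbols and tested with camera as a separate set.

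Alternatives chosen before the data were examined were centring the arrays, scaling them to equal spread, a dye term, a robust variance prior, an ordinary one-sample test, each probe on its own, values of exactly 0 left out, the genes of widest spread (above the 0.9 quantile of the SD) dropped, each array left out in turn, other thresholds, and the array of line 2 left as deposited. Scaling used limma's normalizeMedianAbsValues, the routine that its between-array scale method applies to two-colour log ratios. A first run had passed that method a bare matrix, which it divides by column medians, here near 0, and had called no gene; it was replaced after its result had been seen, because it does not equalise the spread. A log base of 2 and tests of all spots were added after the data had been seen. The counts of the latter first took in spots without a listed gene, and were limited to spots with 1 listed gene after both had been seen, so that they can be set beside the count of genes. The fit was tested on simulated data with the observed spreads, in which 200 of 9253 genes were changed, over 20 runs. It recovered 52.5%, 79.9% and 92.7% of the genes changed by 1, 2 and 3 on the log2 scale, and on average 7.4 of 157.2 calls were false. Noise in the simulation was independent between genes and of the same size on the 3 arrays, without a dye effect or a shared deviation of the wild type. The observed SDs, each from 3 values, were taken as true and given to genes at random. Recovery and false calls on the real arrays may differ. The shares therefore do not describe changed genes of wide spread. One such gene, DFR, had a mean log2 ratio of 4.55 ± 1.58 and was not called. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.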

Results

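Transcript levels at the base of the inflorescence stem were measured on 3 two-colour arrays. Each compared 1 of 3 nst1-1 nst3-1 double mutant samples, called lines here, with wild type. NST1 and NST3 encode NAC transcription factors of secondary wall formation, and the labels describe the mutant as failing to form secondary xylem in the stem and hypocotyl. The comparison asked which transcripts differ between the mutant stem base and the wild type. Values were obtained for 9253 genes on all 3 arrays, and the number of arrays limits the precision. No probe was listed for NST1 or NST3, so the targeted transcripts were not analysed here and the labels were not checked through them. The direction, mutant over wild type, rests on the dyes in the labels and on reading the deposited ratios as Cy5 over Cy3, which no value here tests. The opposite sign of the array with the opposite dye orientation shows only how the arrays stand to each other. Fold values rest on reading the deposited ratios as log10.

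Among the genes past the threshold, more were lower in the mutant than higher. With limma at a Benjamini-Hochberg adjusted p under 0.05, 241 genes fell and 73 rose, and all 314 had the same sign on all 3 arrays. The median log2 ratio was -1.18 among the genes that fell and 0.76 among those that rose, against 0.013 over all genes. Without any test, 133 genes were at least 2-fold lower on every array and 16 at least 2-fold higher. At an unadjusted p under 0.05 there were 2386 genes, and here more were higher (1288) than lower (1098). The share of lower genes was 76.8% of the 314, 66.2% of 524 with arrays scaled to equal spread, and 55.0% of 1178 at an adjusted p under 0.1. It was 53.2% of 1132 with the genes of widest spread dropped and 50.4% of 1157 without line 1.

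The largest decrease among the called genes was that of AT1G19230, a gene of the respiratory burst NADPH oxidase family, with a mean log2 ratio of -4.17 ± 0.42 (SD, n = 3 lines; limma adjusted p = 0.00917), or 18.1-fold lower. AT1G22480, which encodes a cupredoxin-like protein, fell by 4.02 ± 1.12 on the log2 scale, and AT3G62730 fell by 3.99 ± 1.1, both with a limma adjusted p of 0.0426. AT3G56230, which encodes a BTB/POZ-domain protein, had a mean of -3.81 ± 0.33. AT1G56720, for a protein kinase, was at -3.38 ± 0.27. AT4G26580, for a RING-domain protein, was at -3.37 ± 0.22, and AT2G03200, for an aspartyl protease, at -3.31 ± 0.16. Line by line, AT2G03200 measured -3.17, -3.27 and -3.49.

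Increases among called genes were smaller, though DFR, 3AT1 and UGT79B1, which were not called, had higher means (below). Of the called genes ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose most, with a mean log2 ratio of 2.13 ± 0.64 (SD, n = 3 lines; limma adjusted p = 0.0468), or 4.38-fold. Its limma adjusted p was 0.0508 with the arrays scaled to equal spread. YUC6 (AT5G25620), a flavin monooxygenase of auxin biosynthesis, rose by 1.85 ± 0.53 (limma adjusted p = 0.0449). AT5G04000 rose by 1.69 ± 0.36 and AT1G36060, an AP2/ERF-type transcription factor, by 1.63 ± 0.40. AT1G15870 rose by 1.58 ± 0.40, AT4G25980, a peroxidase gene, by 1.52 ± 0.31, and AT4G21910, a MATE transporter gene, by 1.49 ± 0.13. FD (AT4G35900), the bZIP factor that acts with FT in flowering, rose by 1.29 ± 0.24.

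Among the wall lists, every measured gene of xylan synthesis fell. Only 3 of the 23 listed xylan genes were measured, and all 3 were called both over all genes and adjusted over the list alone. IRX15 (AT3G50220) and its homologue IRX15-L (AT5G67210), both needed for normal xylan in secondary walls, had mean log2 ratios of -2.14 ± 0.23 and -1.43 ± 0.07 (SD, n = 3 lines), with a limma adjusted p of 0.0126 for each. IRX10-L (AT5G61840), a xylan xylosyltransferase gene, was at -0.60 ± 0.06 (limma adjusted p = 0.0483, or 0.0508 with a robust variance prior). HCT (AT5G48930), the hydroxycinnamoyl transferase of lignin monomer synthesis, was the 1 measured gene of the 16 on the monolignol list. It fell 5.29-fold, with a mean log2 ratio of -2.40 ± 0.17 and line values of -2.56, -2.23 and -2.42 (limma adjusted p = 0.00917).

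The list of laccases and peroxidases, oxidases of lignin polymerisation and other wall reactions, had 6 measured members, all of them peroxidases, of which 1 rose and 5 were not called. PRX17 (AT2G22420) rose by 0.68 ± 0.10 on the log2 scale (limma adjusted p = 0.0458). PRX71, PRX72 and PRX66 had means of 0.98 ± 0.35, 0.64 ± 0.24 and -1.31 ± 0.51, with limma adjusted p-values of 0.0613, 0.0738 and 0.0627. PRX71 and PRX66 passed with scaled arrays (0.0411 and 0.0419) and with values of exactly 0 left out (0.0494 for each). With the genes of widest spread dropped they passed too (0.0205 and 0.0206), as did PRX72 (0.0297) and PRX25 (0.0232), the last named after its values had been seen. That setting drops genes by the same SD that enters the test, which favours a pass for those kept. Passing there is no added support. Adjusted over the list alone, 4 members were higher and 2 lower. The list was not called by camera (adjusted p = 0.195). The secondary-wall cellulose, secondary-wall transcription factor, vessel, xylem cell death and fibre fasciclin lists had no gene among those measured and were not analysed here.

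**Figure D1:**
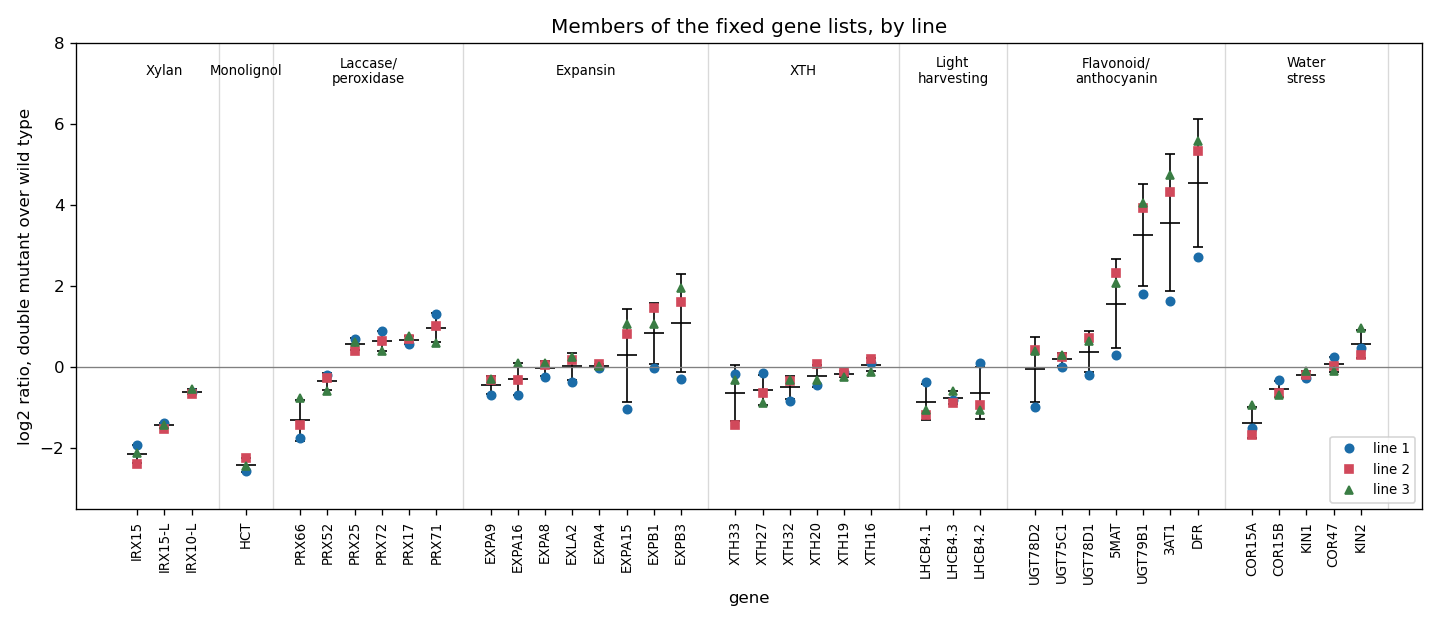
Log2 ratios of double mutant over wild type (vertical axis) for the measured members of 8 of the fixed gene lists (horizontal axis), with 1 point per line and black bars for the mean ± SD of 3 lines. The 3 xylan genes and HCT lie below 0 in every line, while DFR, UGT79B1 and 3AT1 are nearer 0 in line 1 than in lines 2 and 3.

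Genes of anthocyanin synthesis had the highest mean ratios of any fixed list, but none of the 7 measured members passed the test over all genes, and 4 were higher adjusted over the list alone. DFR (AT5G42800), dihydroflavonol reductase, had a mean log2 ratio of 4.55 ± 1.58 (SD, n = 3 lines; limma adjusted p = 0.0511), with line values of 2.73, 5.35 and 5.58. The anthocyanin glycosyltransferase UGT79B1 (AT5G54060) was at 3.26 ± 1.26, the acyltransferase 3AT1 (AT1G03940) at 3.57 ± 1.68, and the malonyltransferase 5MAT (AT3G29590) at 1.57 ± 1.09. The limma adjusted p-values of these last genes were 0.058, 0.0738 and 0.137. The other measured members, named after their values had been seen, had smaller means. UGT78D1 was at 0.39 ± 0.51, UGT75C1 at 0.19 ± 0.15 and UGT78D2 at -0.05 ± 0.80. The median of the list was 1.57, and against all other genes it was higher by camera (adjusted p = 0.0123), a call lost with an estimated correlation (adjusted p = 0.448). That setting also has fewer degrees of freedom. Without the array of line 1, DFR, UGT79B1 and 3AT1 each had a limma adjusted p of 0.0175, and 5MAT one of 0.0178. UGT78D1, named after its values had been seen, had one of 0.0345, so 5 of the 7 passed there. That fit kept the arrays most alike, those of lines 2 and 3, and called 1157 genes in all. No gene passed without line 2 or without line 3. With all arrays kept, DFR also passed with centred arrays (limma adjusted p = 0.0470) and with values of exactly 0 left out (0.0402), as did UGT79B1 in the latter (0.0444).

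Genes of growing primary walls gave no call. None of the 8 measured expansins, which loosen primary walls, was called over all genes or over the list alone, and the camera adjusted p was 0.966. EXPB3 and EXPB1 had means of 1.09 ± 1.21 and 0.84 ± 0.76, and EXPA9 and EXPA16 means of -0.43 ± 0.23 and -0.29 ± 0.39. The 6 measured XTH genes, whose enzymes cut and rejoin xyloglucan, were likewise not called singly, with a camera adjusted p of 0.0748 and a median log2 ratio of -0.36. XTH33, XTH27, XTH32 and XTH20 had means of -0.64 ± 0.69, -0.55 ± 0.37, -0.49 ± 0.29 and -0.22 ± 0.27. COB, the measured gene of primary-wall cellulose, was at 0.26 ± 0.47. Without the array of line 1, limma called EXPB3 (1.78, adjusted p = 0.0223), EXPB1 (1.26, adjusted p = 0.0322), COB (0.53, adjusted p = 0.0472), XTH27 (-0.76, adjusted p = 0.0392) and EXPA15 (0.95, adjusted p = 0.0336), the last named after its values had been seen. Leaving out line 2 or line 3 instead, limma called no gene.

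Of 3 measured light-harvesting genes, which mark green cortex, 1 fell along with the wall genes. LHCB4.3 (AT2G40100) fell by 0.75 ± 0.16 on the log2 scale (limma adjusted p = 0.0483, or 0.0502 with a robust variance prior), while LHCB4.1 and LHCB4.2 were not called, at -0.86 ± 0.44 and -0.63 ± 0.63. Adjusted over the list alone, 2 were lower. Without line 1, all 3 passed, with LHCB4.1 at -1.11 and LHCB4.2 at -0.99 (limma adjusted p = 0.0223 and 0.0249). No gene, LHCB4.3 included, passed without line 2 or without line 3. LHCB4.1 also passed with the genes of widest spread dropped (limma adjusted p = 0.0391), which favours a pass by construction. Markers of other tissues were each represented by 1 gene and were not called. The phloem sugar transporter SWEET11 measured 2.28, 0.16 and -0.50 in lines 1, 2 and 3. CLE41, a peptide gene of the phloem and cambium, was at 0.01 ± 0.34, and the wax synthase gene WSD1 at -0.03 ± 0.08. Both Aurora kinase genes of the cell cycle list were not called, AUR1 at 0.10 ± 0.34 and AUR2 at 0.04 ± 0.82.

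Among the stress and hormone lists, COR15A (AT2G42540), a cold- and drought-induced chloroplast protein gene, fell by 1.36 ± 0.39 on the log2 scale (limma adjusted p = 0.0469, or 0.0519 without line 1). The other 4 measured water-stress genes were not called over all genes, among them KIN2 at 0.59 ± 0.35, COR15B at -0.54 ± 0.20 and KIN1 at -0.18 ± 0.09. COR15B passed without line 1 (-0.66, limma adjusted p = 0.0346) and with the genes of widest spread dropped (0.0339), which favours a pass by construction. Like every gene, it did not pass without line 2 or without line 3. Adjusted over the list alone, 1 was higher and 2 were lower, and the list was not called by camera (adjusted p = 0.226). The jasmonate-responsive defensin gene PDF1.2 was at 0.03 ± 0.41, and the auxin-responsive genes IAA29 and GH3.3 were at 0.19 ± 0.53 and -0.14 ± 0.13, none of them called. Salicylate defence genes were not analysed here, as none was among those measured. The reference genes TIP41L, EF1A and UBC21 were at 0.29 ± 0.04, 0.17 ± 0.22 and -0.07 ± 0.24, also not called.

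The arrays of lines 2 and 3 were closer to each other than either was to that of line 1. Across genes, which are not independent replicates, the Pearson correlation of log2 ratios was 0.784 for lines 2 and 3, 0.488 for lines 1 and 2, and 0.477 for lines 1 and 3. The Spearman correlations were 0.678, 0.366 and 0.414. The ratio differed by more than 2-fold for 153 genes between lines 2 and 3, for 633 between lines 1 and 2, and for 607 between lines 1 and 3.

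**Figure D2:**
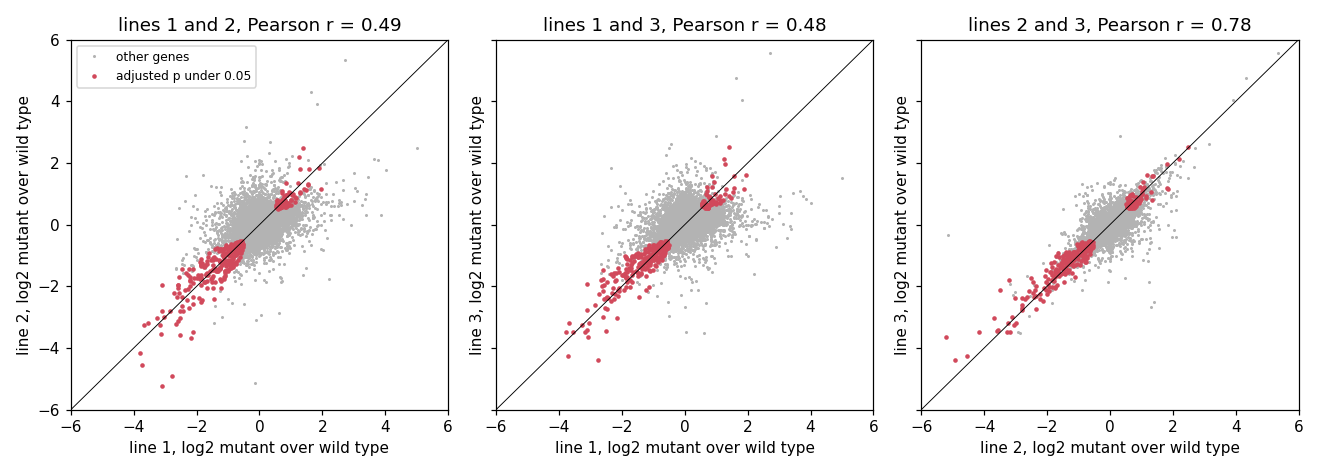
Log2 ratios of double mutant over wild type in each pair of lines, 1 point per gene, both axes on the log2 scale with the line of equality. Red points mark the 314 genes with a limma adjusted p under 0.05, and the points of lines 2 and 3 (Pearson r = 0.784) spread less around equality than those of the other pairs (0.488 and 0.477).

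The count of 314 rose to 524 with scaled arrays, 511 with values of exactly 0 left out, 1132 with the genes of widest spread dropped and 1157 without line 1. When spots without a listed gene were fitted too, leaving out those that follow the dye, 88 of 9333 spots with 1 listed gene passed, 6 higher and 82 lower. No gene passed with a dye term (limma, 1592 at an unadjusted p under 0.05), without line 2 (1373) or without line 3 (1430), and the ordinary one-sample test called 1 gene, AT3G05320, which is not among the 314. The ratios of the 314 stayed about as large: their median absolute log2 ratio was 1.08, and 1.09 with the dye term, 1.03 without line 2 and 1.06 without line 3. Their median moderated standard error was 0.097, and 0.106, 0.122 and 0.161 in these fits, with 4.06 total degrees of freedom against 2.90, 2.90 and 3.98. HCT had log2 ratios of -2.36, -2.49 and -2.40 there, with standard errors of 0.102, 0.118 and 0.174 against 0.1001, and IRX15 ratios of -2.20, -2.02 and -2.15.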

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

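The tests on spots without a listed gene were chosen after the values had been seen, and the criterion for the sign patterns was set after their counts had been seen. Spots without a listed gene took no part in the comparison of mutant and wild type, yet many changed. Leaving out the one-sided spots described next, 202 of 12631 such spots were at least 2-fold lower in the mutant on all 3 arrays and 46 at least 2-fold higher. In a limma fit of all remaining spots, 128 of them were lower and 17 higher at an adjusted p under 0.05. That is 1.15% of these spots, against 0.943% of the 9333 spots with 1 listed gene in the same fit (6 higher and 82 lower). Which genes they measure was not analysed here.

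A further 230 spots without a listed gene had deposited log ratios beyond 0.25 with the same sign on all 3 arrays before any array was turned. All 230 were negative, with medians of -1.91, -2 and -1.95 for lines 1, 2 and 3. A ratio that follows the dye and not the genotype was seen at 2 of the spots with 1 listed gene. What the 230 spots are was not analysed here, and no biological explanation was tested.

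The count of 314 called genes was set against the other sign patterns of the 3 arrays. There are 4 patterns, mirror images counted once, and 1 of them, the real one, gave as many calls. The highest of the others gave 0 calls by limma, with 501, 92 and 26 genes at an unadjusted p under 0.05. With 4 patterns the share cannot fall under 0.05. At least 2-fold changes in the same direction on all 3 arrays numbered 149 in the real pattern and at most 4 in the others. Turning 1 array opposes its signs to those of the arrays it correlates with. Low counts in the other patterns therefore follow by construction, and neither contrast tests chance.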

How the results depend on the processing

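All 314 called genes had 1 sign on all 3 arrays, so their direction could not turn under scaling, the dye term, the robust prior, the ordinary test, a log base of 2 or a left-out array, and keeping it there says nothing about stability. It also did not turn with centring, each probe on its own, zeros left out or the array of line 2 as deposited, nor in the 303 still tested with the genes of widest spread dropped. The causes of the differences below were not tested unless stated. Genes called higher and lower numbered 73 and 241. Both were 0 with the dye term, which leaves 1 residual degree of freedom (smallest adjusted p 0.0989), and with the array of line 2 as deposited, where opposed signs cancel by construction. The ordinary test gave 0 and 1 (AT3G05320, SD 0.00038). Scaling gave 177 higher, zeros left out 164, and dropping the genes of widest spread, which removes variable genes by construction, 530 and 602. Without 1 line the ranges were 0 to 574 higher and 0 to 583 lower: all 314 calls were lost without line 2 (smallest adjusted p 0.166) or line 3 (0.0684), and 313 were kept among 1157 without line 1, each fit having only 2 arrays. Thresholds of 0.01 and 0.1 gave 0 and 24, and 530 and 648; a 2-fold mean gave 17 and 154. Fitting all spots, chosen after seeing the data, gave 3 higher and 66 lower among the spots with 1 listed gene, or 6 and 82 without the one-sided spots.

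Genes at least 2-fold higher on every array numbered 16, and 7 with the genes of widest spread dropped, 21 to 95 without 1 line, 0 with line 2 as deposited and 0 at a log base of 2, chosen after seeing the data; those lower numbered 133, and 2 in each of these last 2 settings. List members called higher numbered 1 (PRX17) and those lower 6. Higher were 2 when centred (with DFR), 2 when scaled (with PRX71), 4 with zeros left out (with PRX71, DFR and UGT79B1), 4 with those dropped (with PRX71, PRX72 and PRX25), 7 at 0.1, 0 to 10 without 1 line, and 0 at 0.01, at a 2-fold mean, with the dye term, by the ordinary test and with line 2 as deposited. Lower were 0 to 9 without 1 line, 1 at 0.01 (HCT), and 0 in the last 3 settings.

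The camera adjusted p of the flavonoid list, 0.0123, was 0.448 with an estimated correlation and 0.947 in the opposite direction with line 2 as deposited; its 10 camera alternatives ranged from 3.36e-06 to 0.947. Fry, which tests a list against no change and not against other genes, gave 0.152 for this list and 0.0436 for the peroxidases, whose camera adjusted p ranged from 0.172 to 0.932 over 11 alternatives. The XTH list ranged from 0.0369 to 0.144 without 1 line and from 0.0369 to 0.448 over 11 camera alternatives. Over the named genes and settings, 190 calls were lost, 25 were gained and 0 reversed, with genes picked after their values were seen included. All 37 named genes called in the main fit were lost without line 2, without line 3 and with the dye term. The same held for the ordinary test and for line 2 as deposited. The rest of the losses were 1 with scaling, 3 with the robust prior and 1 without line 1. In 20 cases a named gene that neither setting called changed sign. Values were present on all 3 arrays for every gene, so the setting with at least 2 arrays was not run. The targeted genes gave no value in any setting. Each ratio sets mutant against wild type within 1 array, so the test of the 3 ratios keeps that pairing by array. It is a pairing by hybridisation only, since whether each mutant sample had its own wild-type extract is not known. Without spot intensities, signal over background could not be examined.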

Other observations

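The tests and the genes of this part were chosen after the values had been seen, except that the gene families were formed before their values were known. Other called decreases, picked after their values were seen, included the following genes. TBL33 (AT2G40320) and TBL32 (AT3G11030), which encode xylan acetyltransferases, fell, with mean log2 ratios of -3.19 ± 0.13 and -1.94 ± 0.23 (SD, n = 3 lines) and limma adjusted p-values of 0.00917 and 0.0143. They were the called members of 17 measured TBL genes, and the family was not called by camera (adjusted p = 0.225). AT4G39230, AT1G75280 and AT1G19540, relatives of isoflavone and phenylcoumaran reductases, fell too, at -2.54 ± 0.23, -2.49 ± 0.15 and -2.63 ± 0.34. AT1G79620, a receptor-like kinase gene, fell by 2.33 ± 0.32, and AT2G28315, a nucleotide-sugar transporter gene, by 2.07 ± 0.45. The cytosolic glyceraldehyde-phosphate dehydrogenase gene GAPC2 fell by 1.21 ± 0.22 (limma adjusted p = 0.0359).

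Of the 38 families formed from symbols, 2 were called by camera, and both were higher. The 12 measured subunits of nuclear RNA polymerases (NRP) had a median log2 ratio of 0.34 and line means of 0.35, 0.39 and 0.26 (adjusted p = 0.0139), with 0 members called by limma over all genes and 6 adjusted over the family alone. The 6 measured LSM genes, whose products bind RNA in splicing and decay, had a median of 0.38 (adjusted p = 0.0404), with LSM3A called (0.67, limma adjusted p = 0.0449). Both family calls were lost in camera with an estimated correlation (adjusted p = 0.954 for each). That correlation was 0.14 for NRP but negative, at -0.11, for LSM. Correlation between members therefore did not cost LSM its call. The fewer degrees of freedom of that setting apply to both families. Fry, which tests a family against no change, gave an adjusted p of 0.158 for NRP and 0.0897 for LSM. With arrays centred and scaled the medians were 0.33 and 0.33 for NRP and 0.36 and 0.37 for LSM.

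Of 18 photosynthesis genes picked by symbol after the ratios had been seen, 3 of them on the light-harvesting list, 6 fell by limma: PRK (-1.25), SBPASE (-1.13), PSBW (-1.12), PSAN (-1.10), NdhS (-0.87) and LHCB4.3 (-0.75). The rest were not called, among them PGRL1B at -0.011 and CRR28 at 0.093, and because of how they were picked, the 18 do not show that photosynthesis genes are lower as a class. For these 18, dye bias as the whole cause is argued against. A ratio that follows the dye and is lower in lines 1 and 3 would be positive on the turned array of line 2. Their mean there was -0.95, against -0.50 and -0.71 for lines 1 and 3. Of the 18, 15 were lower on all 3 arrays, as were 23.9% of all genes. The picking may have left out genes that follow the dye, so this holds for these 18 only. A shift of whole arrays moves every gene alike, so it cannot make the gap between the median of -0.69 for the 18 and 0.013 for all genes. The median of the 18 was -0.70 with arrays centred and -0.71 scaled. Because the 18 were picked for their ratios and the arrays were centred or normalized before deposit, these values do not test whether a shift lowered all genes. Less green tissue in the mutant stem bases and a change within green cells may each account for the lower ratios of the 18. A deviation of the wild-type RNA may do so too, if it was 1 extract on all 3 arrays. Members ranged from -1.79 (RCA, limma adjusted p = 0.0627) to 0.093. No value gives the tissue share, and these causes cannot be told apart.

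Line 1 differed more from lines 2 and 3 than these did from each other, also in the means of families: the 10 tubulin genes had line means of -0.98, -0.12 and -0.02, the TBL genes -0.93, -0.16 and -0.20, and the fixed expansin list -0.41, 0.45 and 0.54. Dye orientation is argued against, since the SD of the difference was 0.323 between lines 2 and 3, of opposite orientation, and 0.545 between lines 1 and 3. Compressed ratios on line 1 cannot be decided by the SD over genes, 0.580 for line 1 and 0.506 for line 2, as noise widens it too. DFR was nearer 0 in line 1 (2.73, against 5.35 and 5.58 in lines 2 and 3), while HCT was not (-2.56, against -2.23 and -2.42). Noise independent between probes would give line 1 no larger excess of family means: the size-weighted sum of squared family means of each line's deviation, less its mean over random gene sets, was 44.9 for line 1, against 12.5 and 16.9 for lines 2 and 3, although all 3 lines reached a permutation p of 0.0001, the smallest that 10000 draws give. Each deviation was taken from the mean of the other lines, so that of line 1 also enters those of lines 2 and 3. The 3 p-values are therefore not separate evidence. Probes shared between paralogs, the stage of the stems within 12 to 17 cm, and a true difference between the mutant samples were not tested and stay open.

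The neighbourhood of the insertions was examined for local changes. Among the 10 annotated genes on each side of NST1 and NST3, 10 were measured and 1 was called, AT1G32740, at -1.94 ± 0.09 (one-sided Fisher's exact test, p = 0.292). Among 50 on each side, 67 were measured and 2 were called, AT1G32740 and AT2G47120, against 2.27 for the share of all genes (Fisher's exact test, p = 0.669). With so few measured neighbours, a local effect on a single gene cannot be told apart from the change in the rest of the transcriptome.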
